A study of Mus musculus with 2 samples.

How the data were processed

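RNA captured on oligo-dT beads was profiled in mouse embryos of the C57BL/6 background. They had been injected with an siRNA against Dnmt1, the maintenance DNA methyltransferase, or with a scrambled siRNA. Each group is 1 library made from a pool of 20 embryos at the 4 to 8-cell stage. Per the labels' protocols, mRNA was captured on oligo-dT beads and converted to adapter-tagged cDNA by pico-profiling, a method for very small inputs. The cDNA was amplified by 20 cycles of PCR, made into libraries with a DNA library kit and sequenced from both ends on an Illumina NextSeq. No molecular identifiers are described, so amplified copies of a cDNA cannot be told from separate molecules.

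The deposited table holds counts per gene for 23418 rows named by gene symbol, with 1 column per library. Trim Galore, HISAT2, HTSeq, DESeq2 and the mm9 build are named in the submitters' processing notes, with no versions. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The table is described as DESeq2-normalised, and its counts were taken as the authors deposited them. The DESeq2 size factor recomputed from the table was 1 for both columns, which a table already normalised would also give, so it does not tell the unit. The low values were examined instead, since scaling whole counts up and rounding them skips whole numbers and scaling them down piles them up. In the deposited columns 0 whole numbers from 1 to 59 were skipped, and no value from 2 to 30 was more frequent than 1.23 (siDnmt1) or 1.29 times (scrambled) the mean of its neighbours. Copies of the columns scaled by factors from 0.5 to 0.98 and rounded gave ratios of at least 1.82, and copies scaled by 1.01 to 1.3 skipped at least 1 whole number. Scaling by 0.99, or by a factor below 0.5, is not excluded by this check, which was added after the data were seen. The values were treated as unscaled counts within these limits. Of 10900 genes with a count in both libraries, 5102 were higher in siDnmt1, 5393 were lower and 405 were equal.

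Total counts were 12236615 in the siDnmt1 library and 11675483 in the scrambled library. Rn45s, the ribosomal RNA precursor, held 37.3% and 29.9% of them, which left 7670163 and 8187941 counts for other rows. Names on 27 rows had been turned into dates by spreadsheet software, and 2 of these names stood on more than 1 row. They held 0.0234% and 0.0230% of the counts, stayed in the tests and were not named. All value columns were mapped to a sample by name.

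With 1 library per group there are no residual degrees of freedom, so the edgeR quasi-likelihood test could not be fitted and no p-value was computed. The comparison is descriptive and concerns these 2 libraries. For each gene the log2 ratio was log2((siDnmt1 + 5)/(siScrambled + 5)), which understates the change of genes with low counts. The 7315 genes with a mean of at least 20 counts over both libraries were compared, and genes at least 2-fold apart on this scale were counted. Folds in the text are plain ratios of counts unless called log2. Where an interval is given, it is a 95% Clopper-Pearson interval of the ratio. It covers counting error only and neither amplification nor the differences between pools of embryos. Many folds are given without it, and those that rest on few counts are imprecise. A fold against a library with no count was computed against a floor of 3 counts. It carries no interval and leaves out the counting error of the other library, so it is not a 95% limit.

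Before the data were examined, 30 gene lists, the rule for the genes named and most of the alternatives were fixed. The genes named are Dnmt1, the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 100 counts, and the extremes of each list at a mean of at least 20 counts. The extremes are the 2 highest and 2 lowest members, or the 4 highest and 4 lowest for the lists on DNA methylation, MERVL-linked, imprinted and germline genes. For lists with fewer than 5 such members, all are given. Some genes that this rule takes are not reported here. Other genes named were chosen after their values were seen. A list's median log2 ratio was set against 10000 random lists of the same size, drawn from non-members within 10 bins of mean count. It was said to stand apart when it lay outside the middle 95% of the random medians, that is in the lowest or highest 2.5%. This percentile describes these libraries and is not a test of the siRNA.

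Transcript length and GC content were taken from the longest GENCODE M21 transcript of each symbol, directly or through an unambiguous RefSeq synonym. A length was found for 7270 of the 7315 genes (99.4%). That annotation is on GRCm38, not mm9, so it was used for names, lengths, GC content and chromosome membership, and no coordinates are given. For length-matched lists, each member was replaced by 1 of its 60 nearest genes in length and mean count. A lowess curve with a span of 0.3 was also used to remove the length trend. It was fitted to all genes with a length, list members included, so it can take away part of a list's own difference. Matching was repeated on the median transcript length, on GC content, and on length and GC content together. All length and GC checks and the scaling without Rn45s were added after the data were seen.

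The alternatives were pseudocounts of 1 and 20, no filter or a mean of at least 100 counts, 4 other scalings (equal totals, a median log2 ratio of 0, edgeR TMM factors, equal totals without Rn45s), lowess trends on mean count and on length, a 4-fold threshold, 20 bins and the mean of each list. The size rule was tested on simulated data: Poisson counts for the 7314 genes that passed the mean in that draw, with 200 genes changed 2-fold, gave 39.0% recovered at the 2-fold rule, since the change lay at the threshold. In the draw with 4-fold changes, 7311 genes passed and 99.0% of the 200 were recovered. In each draw 7 unchanged genes passed. These rates hold for counting error alone. In 20 simulations of counting error alone, the median interquartile range of log2 ratios was 0.19, against 1.24 between the deposited libraries. The draws therefore do not tell how many genes past 2-fold in these libraries reflect a change due to the siRNA. Of 300 random lists of 25 genes, 4.3% stood apart, and all lists shifted by a log2 value of -1 did (100.0% of 100). Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.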

Results

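RNA captured on oligo-dT beads was sequenced from 1 pool of 20 mouse embryos injected with siRNA against Dnmt1 (siDnmt1). The other library was from 1 pool of 20 embryos injected with a scrambled siRNA. Both pools were collected at the 4 to 8-cell stage. The series addresses how Dnmt1, the enzyme that copies DNA methylation onto newly replicated DNA, acts on the genome of early embryos. The libraries held 12236615 and 11675483 counts, and 12196 and 12305 genes had at least 1 count. Each group had 1 library, so no difference below has a replicate check, and the intervals given are 95% intervals of counting error alone. Rn45s, the ribosomal RNA precursor and not a messenger RNA, took 37.3% of the siDnmt1 counts and 29.9% of the scrambled counts. Odc1, which encodes ornithine decarboxylase of polyamine synthesis, took 16.5% and 24.5% of what remained. None of the 23418 row names was that of a retroelement family (0 entries), so retroelement transcripts were not analysed here.

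The first question was whether the targeted transcript was lower after siRNA injection. Dnmt1 had 687 counts in the siDnmt1 library and 847 in the scrambled library, 1.23-fold lower (95% interval 1.11 to 1.37). The difference exceeded the counting error of independent counts but not the spread between these libraries. Of the 7315 genes compared, 38.3% had a log2 ratio at or below that of Dnmt1 (-0.30). Uhrf1, which brings Dnmt1 to hemimethylated DNA, had 58 counts against 380 and was 6.55-fold lower (4.96 to 8.79). Dnmt3l, the cofactor of the de novo methyltransferases, was 3.45-fold lower (2.07 to 5.99) and Dppa3, the maternal factor that protects methylation in the zygote, 2.77-fold lower (2.10 to 3.70). Dppa3 has a short transcript (833 nt), and its log2 ratio of -1.41 was -0.19 after the trend with transcript length was removed. Higher in siDnmt1 were Mbd4, a thymine glycosylase of methylated sites, at 2.71-fold (2.06 to 3.60), and Tet2, a methylcytosine dioxygenase, at 1.90-fold (1.72 to 2.11). Mbd1 was 1.92-fold and Usp7, a deubiquitinase, 1.80-fold higher. Of the 17 measured genes of the DNA methylation machinery, 1 was at least 2-fold higher and 3 were at least 2-fold lower. Their median log2 ratio of 0.31 lay at percentile 90.4 of random lists matched on mean count.

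Across all genes, 911 of 7315 were at least 2-fold higher in siDnmt1 and 1221 were at least 2-fold lower, and the other 5183 lay within 2-fold. Among genes with a mean of at least 100 counts, the largest ratio upward was that of Vipas39, a gene of endosomal sorting, with 269 counts against 23 (11.7-fold, 7.63 to 18.8). Eepd1 followed at 11.2-fold. Zranb3, a helicase that remodels stalled replication forks, was 7.89-fold higher, Usp11, a deubiquitinase, 7.96-fold, and Lpin3, a phosphatidate phosphatase, 7.79-fold. Mlxip, which encodes the glucose-responsive transcription factor MondoA, had 1126 counts against 174 (6.47-fold, 5.51 to 7.64). Hbs1l, a factor that rescues stalled ribosomes, was 6.46-fold higher. The others of the 12 highest were Paxbp1 (7.46-fold), Wdr91 (7.26-fold), Slc39a11 (7.04-fold), Exoc6b (6.93-fold) and Qsox2 (6.44-fold).

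At the other end of the same genes, Chgb, which encodes the secretory granule protein chromogranin B, had 1 count against 218, a ratio of 218 with a counting interval of 38.7 to 8650. Il4ra, the interleukin 4 receptor chain, had 4 against 196 (49.0-fold lower, 18.8 to 182), and the zinc finger gene Zfp747 had 16 against 336 (interval 12.7 to 37.2-fold lower). Parn, a deadenylase, had 29 against 410 (14.1-fold lower, 9.70 to 21.4). Guk1, guanylate kinase, was 11.8-fold lower, Suclg2, a subunit of succinyl-CoA ligase, 11.9-fold and Fkbp8, a mitochondrial immunophilin, 11.4-fold. Radil, Bnip1, Cnpy3, AI462493 and 2310040G24Rik were 15.3-fold, 14.4-fold, 15.1-fold, 13.2-fold and 11.5-fold lower. The middle 50% of genes spanned log2 ratios of -0.67 to 0.57, a width of 1.24.

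**Figure D1:**
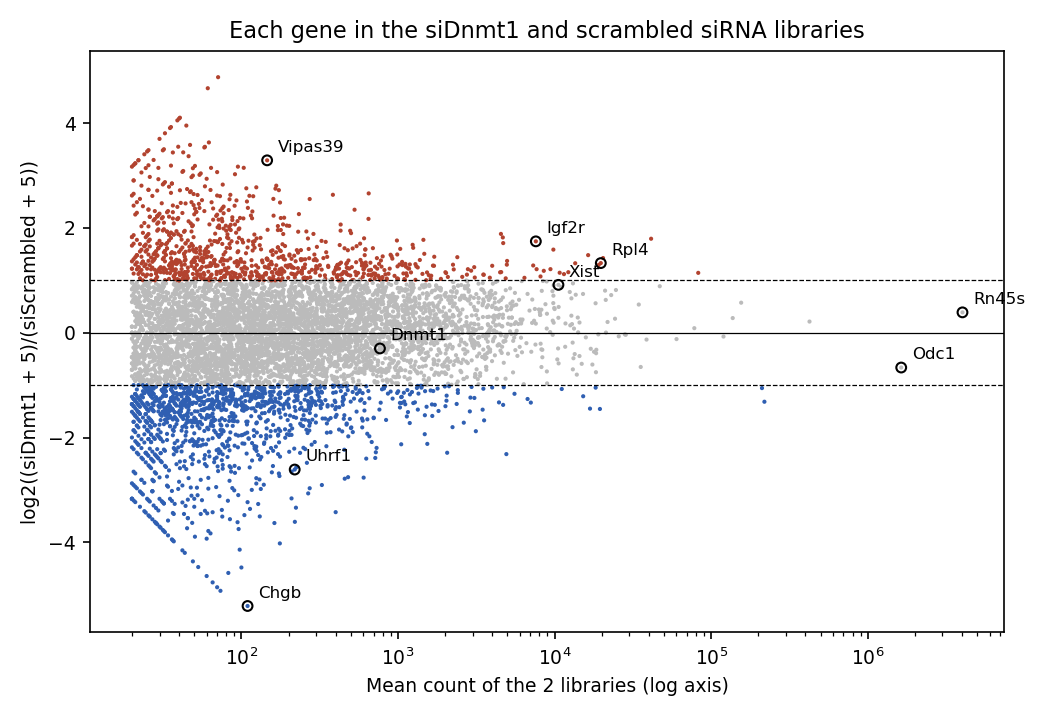
Each point is 1 of the 7315 genes, with the mean count of the 2 libraries on a log x axis and the log2 ratio of siDnmt1 to scrambled on the y axis. Red points (911) are at least 2-fold higher and blue points (1221) at least 2-fold lower in siDnmt1, dashed lines mark 2-fold, and circled genes are labelled, with Dnmt1 at -0.30 and Uhrf1 at -2.61.

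With the filter on low counts, no list of genes tied to embryonic stage had a median that stood apart. The MERVL-linked list did stand apart by its mean and without the filter. The list of MERVL-linked genes, which are expressed at the 2-cell stage from or with an endogenous retrovirus, had 18 of its 45 members in the table at a mean of 20 counts or more. Of these, 7 were at least 2-fold lower and 2 at least 2-fold higher, with a median log2 ratio of -0.23 at percentile 19.8. Zfp352 had 112 counts against 802 (7.16-fold lower, 5.87 to 8.81), Gm20767 had 4 against 119 (29.8-fold lower, 11.3 to 111), Usp17lb was 4.94-fold lower, and BC080695 had 1 count against 44 (ratio 44.0, 7.50 to 1777). Sp110 had 60968 counts against 32953 (1.85-fold higher, 1.83 to 1.88). Snai1, a zinc finger repressor, was 2.69-fold, Zfp560 2.69-fold and Gm13119 2.02-fold higher. The list's mean log2 ratio was -0.57, which lay at percentile 2.43 of random list means, and without the filter on low counts its median of -0.47 lay at percentile 0.71. The members were short (median 1918 nt), and length was taken into account for the filtered median alone, not for the mean or without the filter. That median lay at percentile 65.01 among lists matched on the longest transcript and at 18.1 among lists matched on median transcript length, and it was 0.0091 (percentile 48.47) after the length trend was removed. Many of these genes have near-identical copies, so their counts are uncertain.

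Transcripts stored in the oocyte gave a median of 0.08 over 20 genes, at percentile 72.2. Nlrp9a was 6.92-fold lower and Plat, the tissue plasminogen activator, 3.48-fold lower, while Bub1b, a spindle checkpoint kinase, was 3.81-fold higher (3.11 to 4.70) and Zp1, a zona pellucida gene, 2.09-fold higher. Pluripotency genes had a median of -0.13 over 23 genes (percentile 15.01). Prdm14 had 3 counts against 69 (ratio 23.0, 7.55 to 114) and Dppa5a had 8 against 47 (5.88-fold lower, 2.75 to 14.4). Carm1, a histone arginine methyltransferase, was 3.35-fold higher and Tdgf1, a Nodal coreceptor, 2.11-fold higher. Trophectoderm genes had a median of 0.09 over 21 genes (percentile 63.4). The glucose transporter Slc2a1 had 10 counts against 41 (4.10-fold lower, 2.02 to 9.18) and Krt18 was 2.95-fold lower. Aqp3 was 2.38-fold and Cldn7 1.92-fold higher. Primitive endoderm genes had a median of -0.16 over 8 genes (percentile 37.1). Lama1 was 4.86-fold higher, Lamb1 1.46-fold higher, Sparc 2.44-fold lower and Pdgfra 1.38-fold lower.

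Imprinted genes, many of whose parental alleles are distinguished by DNA methylation, were examined by parental origin. The counts do not separate the alleles of a gene. The 9 measured genes of the paternally expressed list had a median log2 ratio of 0.90, at percentile 99.3. Of these, 4 were at least 2-fold higher and 0 at least 2-fold lower. The median is the value of 1 member. The next lower member, Kcnq1ot1, had a log2 ratio of 0.18, inside the range of random medians (up to 0.70). The mean of the list, 0.69, lay at percentile 97.9. Sfmbt2, a Polycomb group gene, had 63 counts against 10 (6.30-fold higher, 3.21 to 13.8). Zdbf2 was 2.77-fold higher, Peg3, a zinc finger gene, 2.64-fold and Dhcr7, an enzyme of cholesterol synthesis, 2.56-fold. The list was used as fixed in advance, and the parental origin of Dhcr7 was not checked here. Impact was 1.68-fold lower, and Kcnq1ot1 (1.14-fold higher), Zrsr1 (22 counts against 23) and Slc38a4 (1.36-fold lower, with an interval that includes equality) lay closer to 0. The list had 33 genes in the table, and with no filter on low counts its median was 0.064, at percentile 69.56, so that it no longer stood apart. Kcnq1ot1 and Zrsr1 overlap other genes and the strand setting of the counting is not known, so their counts are uncertain.

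The 9 maternally expressed imprinted genes had a median of 0.21, at percentile 74.9. Igf2r, the receptor that clears insulin-like growth factor 2, had 11698 counts against 3488 (3.35-fold higher, 3.23 to 3.48). Copg2 was 2.57-fold, H13 1.59-fold and Trappc9 1.29-fold higher. Phlda2 had 0 counts against 64, 21.3-fold lower when set at the floor of 3 counts, and Grb10, Ppp1r9a and Nap1l4 were within 1.29-fold. The difference between the 2 imprinted lists was not tested. Germline genes that DNA methylation keeps silent in somatic cells had a median of -0.06 over 23 genes (percentile 57.9), with 3 at least 2-fold higher and 5 at least 2-fold lower. Sohlh2, a germ cell transcription factor, had 64 counts against 5 (12.8-fold higher, 5.21 to 40.8), Magea5 was 4.91-fold, Tdrd1 2.68-fold and D1Pas1 1.82-fold higher. Syce2, a gene of the synaptonemal complex, had 0 counts against 40, 13.3-fold lower when set at the floor of 3 counts. Fkbp6, Tex19.1 and Rpl10l were 4.79-fold, 3.18-fold and 3.31-fold lower. Xist, the noncoding RNA that coats the inactive X chromosome, had 13830 against 7339 counts (1.88-fold higher, 1.83 to 1.94), and Rlim, its activator, was 1.20-fold higher. Counts of Xist are uncertain in the same way, since Tsix is transcribed across it. The log2 ratio of Xist, 0.91, lay at percentile 85.74 of the genes compared. No sex is recorded for the embryos, so the share of females in each pool is not known.

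Factors that silence retroelements had a median log2 ratio of -0.04 over 27 genes (percentile 33.8). Zfp91 was 2.91-fold and the heterochromatin protein gene Cbx5 1.95-fold higher, and Cbx1 was 2.73-fold lower. Genes of the interferon and viral RNA response had a median of -0.12 over 11 genes (percentile 43.9), with Irf7 at 106 counts against 11 (9.64-fold higher, 5.17 to 19.9), Dtx3l 1.93-fold higher with an interval that includes equality, Bst2 4.57-fold lower and Ifi35 at 11 counts against 33. The p53 targets and apoptosis genes had a median of 0.17 over 23 genes (percentile 78.2). Cdkn1a, the cyclin-dependent kinase inhibitor p21, was 2.35-fold higher (2.10 to 2.63) and Sesn2 1.74-fold higher. Sesn1 had 9 counts against 52 (5.78-fold lower, 2.82 to 13.3) and Plk2 was 1.78-fold lower.

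Cytosolic ribosomal protein genes had a median log2 ratio of -1.23 over 60 genes, and 34 were at least 2-fold lower against 3 at least 2-fold higher. Rps29 had 0 counts against 147, 49.0-fold lower when set at the floor of 3 counts. Rps23 had 1 against 42 (ratio 42.0, 7.14 to 1698), whereas Rpl4 had 28238 against 11234 (2.51-fold higher) and Rps15a was 2.51-fold higher. Nuclear genes of oxidative phosphorylation had a median of -1.20 over 21 genes, with 13 at least 2-fold lower and 0 at least 2-fold higher. Atp5o had 6 counts against 55 (9.17-fold lower, 3.95 to 26.1) and Ndufa11 was 5.62-fold lower, while Ndufs8 was 2.06-fold and Atp5a1 1.35-fold higher. Proteasome genes had a median of -0.53 over 29 genes, with 9 at least 2-fold lower and 1 at least 2-fold higher. Psmb1 had 9 counts against 183 (20.3-fold lower, 10.5 to 45.2) and Psmb6 was 5.13-fold lower, while Psmd3 was 2.02-fold and Psmd1 1.59-fold higher. The ribosomal protein and oxidative phosphorylation medians lay at percentile 0.00 of the 10000 random lists and the proteasome median at 0.13. The members of these lists had short transcripts, with median lengths of 1082, 1232 and 1819 nt, and log2 ratios of short genes were lower in general. After removal of the length trend the medians were -0.15 for ribosomal protein genes (percentile 14.03), -0.52 for oxidative phosphorylation (2.43) and -0.054 for proteasome genes (27.9). Many ribosomal protein genes have processed pseudogenes, which makes their counts uncertain.

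Genes of RNA interference were higher as a group. Their median log2 ratio was 0.78 over 14 genes, at percentile 99.9, with 5 at least 2-fold higher and 0 at least 2-fold lower. Eif2c3, an Argonaute gene, was 3.58-fold higher (1.86 to 7.47) and Mov10, an RNA helicase of silencing complexes, 2.82-fold higher (2.48 to 3.21). Tnrc6c was 1.59-fold lower and Dgcr8, a subunit of the microRNA processor, 1.35-fold lower. The members had a median length of 6882 nt.

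Genes of S phase and G2/M had a median of -0.29 over 51 genes, at percentile 0.89, with 8 at least 2-fold lower and 5 at least 2-fold higher. Gmnn, which encodes the replication licensing inhibitor geminin, was 4.86-fold lower, and Fzr1, an activator of the anaphase-promoting complex, 4.42-fold lower. Bub1, a mitotic checkpoint kinase, was 4.32-fold higher, and Mcm6, of the replicative helicase, had 14743 counts against 4905 (3.01-fold higher). The mean of this list, -0.19, lay at percentile 7.96 and did not stand apart. RNA polymerase II and splicing genes had a median of -0.30 over 39 genes (percentile 1.94). Gtf2b had 6 counts against 60 (10.0-fold lower, 4.34 to 28.3) and Snrpc was 5.92-fold lower, while Sf3b3 was 2.23-fold and Polr2b 1.97-fold higher. After removal of the length trend the median of this list was 0.022, at percentile 43.05.

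The medians of the other groups lay within the range of matched lists. Heat shock and chaperone genes had a median of -0.05 over 24 genes (percentile 29.1), with Hsf2 3.29-fold and Cct6a 2.31-fold higher, Cct4 2.51-fold lower and Hspe1 at 14 counts against 42. Glycolysis genes had a median of 0.07 over 15 genes (percentile 66.2), with Pfkm 6.87-fold and Slc2a1 4.10-fold lower and Slc16a1 2.67-fold and Pfkp 2.14-fold higher. Histone and chromatin assembly genes had a median of -0.12 over 15 genes (percentile 20.1), with Asf1a, a histone chaperone, 3.69-fold and the histone variant gene H2afz 2.77-fold lower and Supt16 1.66-fold and Chaf1a 1.46-fold higher. The mean of this list, -0.46, stood apart at percentile 1.57. The housekeeping list had a median of -0.30 over 13 genes (percentile 12.9). Gusb had 9 counts against 36 (4.00-fold lower, 1.89 to 9.44), while H2afz was 2.77-fold lower and Polr2a 1.23-fold higher. Without the filter on low counts the housekeeping median was -0.59 and stood apart. In all, 7 of 22 lists stood apart, 5 lower and 2 higher, where 1.10 would by chance. That number holds for lists of unrelated genes matched on mean count alone. Matched on length and mean count, oxidative phosphorylation (percentile 3.90), proteasome (24.06) and RNA polymerase II and splicing genes (12.42) no longer stood apart. The mean and the median of a list differed in sign for retroelement silencing (mean 0.03), maternal (-0.03), trophectoderm (-0.17), primitive endoderm (0.06) and glycolysis genes (-0.27). The medians of 3 lists near 0, chaperones, germline genes and retroelement silencing factors, changed sign with the scaling of the libraries.

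**Figure D2:**
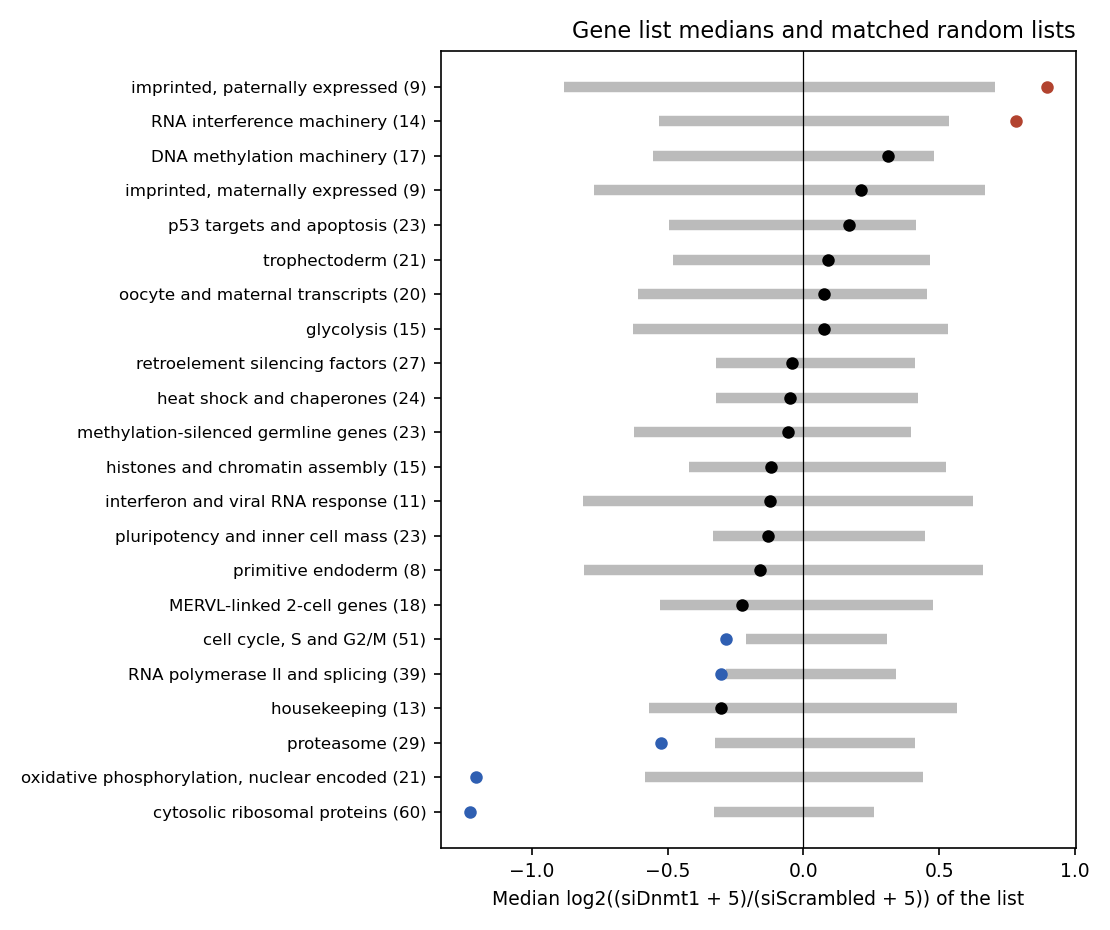
Points give the median log2 ratio of siDnmt1 to scrambled for each of 22 gene lists (number of measured genes in brackets), and grey bars the middle 95% of 10000 random lists matched on mean count. Red (2 lists) and blue (5 lists) points lie outside the bars, from -1.23 for ribosomal protein genes to 0.90 for paternally expressed imprinted genes.

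The ratio between the libraries varied with transcript length. Across 7270 genes, which are not independent replicates, the log2 ratio had a Spearman rho of 0.24 and a Pearson r of 0.24 with log2 length of the longest transcript, and a rho of -0.11 with its GC content. Genes were split into 10 groups by length. The group with the shortest transcripts (346 to 1769 nt) had a median log2 ratio of -0.78, with 315 genes at least 2-fold lower and 33 at least 2-fold higher. The group with the longest (from 7413 nt) had a median of 0.19, with 53 lower and 99 higher. Of 101 named genes past 2-fold, 9 came inside it when the trend was removed, all of them lower in siDnmt1 before: Dppa3, H2afz (log2 ratio -1.47 before and -0.48 after), Dppa5a (-2.00 and -0.53), Bst2 (-2.02 and -0.76), Hspe1 (-1.31 and -0.22), Ifi35 (-1.25 and -0.52), Krt18 (-1.35 and -0.68), Rpl10l (-1.61 and -0.57) and Sparc (-1.07 and -0.89). Among lists matched on length as well as mean count, the percentiles were 0.11 for ribosomal protein, 3.90 for oxidative phosphorylation, 24.1 for proteasome, 2.47 for cell cycle, 99.00 for paternally expressed imprinted and 99.7 for RNA interference genes. The result depended on the length used: the median transcript length of each gene had a lower rho of 0.13, and matching on it gave percentiles of 0.00, 0.00, 1.13, 0.95, 99.2 and 99.9 for the same lists in that order.

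**Figure D3:**
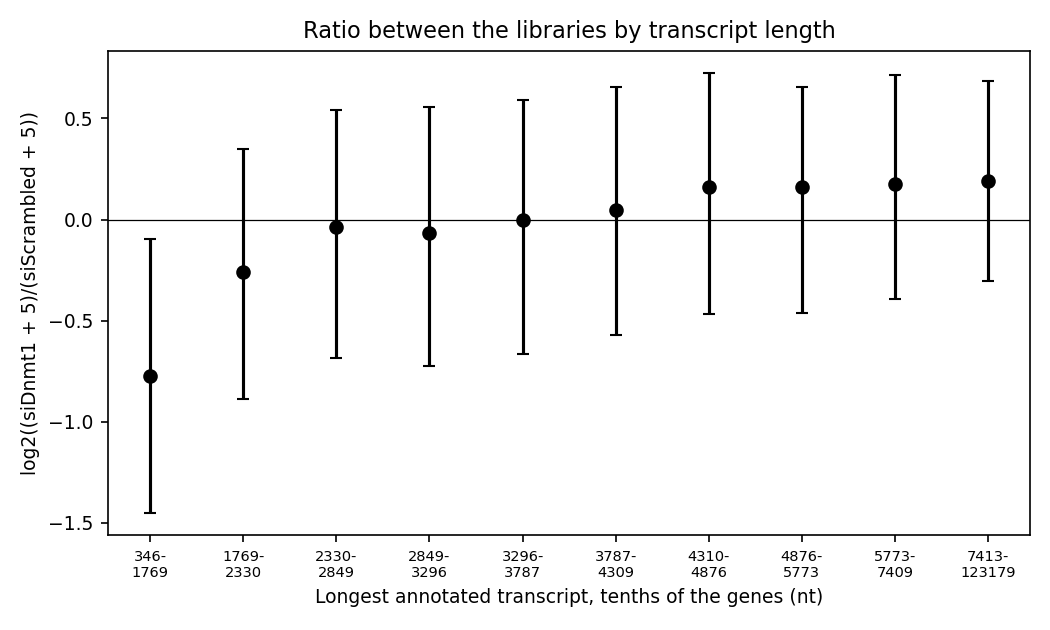
The 7270 genes with a known length are split into 10 equal groups by the length of the longest annotated transcript (x axis, nt), and the y axis gives the log2 ratio of siDnmt1 to scrambled. Points are medians and bars the middle 50% of genes, and the medians run from -0.78 in the shortest group to 0.19 in the longest.

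Markers of other cell types that could accompany embryos were scarce in both libraries. Of 19 cumulus and granulosa cell markers 1 reached a mean of 20 counts, Amhr2 with 45 against 56. Epcam was the single oviduct epithelium marker at that level, with 97 against 258, and the embryo itself expresses this gene. Pecam1, on the list for blood, had 259 against 275 and Odf2, on the list for sperm, had 190 against 180. Among stroma markers, Tagln had 40 counts against 3 (ratio 13.3, 4.25 to 67.4), Fn1 216 against 85, Vim 14 against 38 and Postn 6 against 38, while the collagen genes Col1a1, Col1a2 and Col3a1 had 0 counts in both. The 9 Y-linked genes summed to 40 counts in siDnmt1 and 53 in scrambled, of which Zfy1 gave 0 and 36 and Ddx3y gave 20 and 2. None of the 28 names listed for mitochondrially encoded genes was among the rows, so this measure of RNA quality was not used here.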

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

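Dnmt1 kept its direction under the 8 alternatives run for it, with log2 ratios from -0.45 to -0.21. The count of genes at least 2-fold higher and lower was 1682 and 2122 with no filter on low counts, 395 and 482 at a mean of at least 100 counts, and 193 and 330 at a 4-fold threshold, where the filter and threshold set the number of genes; the other alternatives left both counts within 1.5 times of 911 and 1221. The 4 other scalings moved the median of all genes to between -0.09 and 0.06, and the share of higher genes among those past 2-fold to between 38.1% and 49.1%, from 42.7%. All 911 and 1221 genes had a counting interval that excluded equality. The minimum mean and the 2-fold rule already ensure this, so it adds no support. Of the 7 lists that stood apart, 1, RNA interference, did so under every alternative run. With no filter, the median of paternally expressed imprinted genes was 0.064 (percentile 69.56), while MERVL-linked genes at -0.47 and housekeeping genes at -0.59 stood apart. The length corrections were run with the filter and on medians, so they do not bear on these calls or on those of list means. With list means, MERVL-linked genes at -0.57 and histone and chromatin assembly genes at -0.46 stood apart and cell cycle genes at -0.19 did not. At a mean of at least 100 counts, RNA polymerase II and splicing genes had a median of -0.16 and did not stand apart. Removing the trend on mean count ended the call for RNA polymerase II and splicing (-0.25, percentile 4.65) and cell cycle genes (-0.24, percentile 2.77). Removing the length trend, an alternative added after the data were seen, turned RNA polymerase II and splicing genes to 0.022 and left ribosomal protein genes at -0.15 (percentile 14.03) and proteasome genes at -0.054 (percentile 27.9). Against lists matched on length and mean count, without or with GC content, also added, oxidative phosphorylation (-1.20, percentiles 3.90 and 2.91), proteasome (-0.53, 24.1 and 16.03) and RNA polymerase II and splicing (-0.30, 12.4 and 9.98) did not stand apart. Matching on GC content alone, or on median transcript length, also added, changed the call of 0 lists. Apart from the filter and threshold, the cause of these changes was not tested. No named gene past 2-fold changed sign, and 30 of their values under the alternatives came inside 2-fold, 9 of them with the length trend removed. No paired analysis was possible because each group has 1 library, and no library could be left out. Depth limits the genes with few counts: a count of 0 to 3 in one library leaves a wide or one-sided ratio, and the interval covers counting error alone.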

Other observations

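The tests of families, chromosomes, parity, length, GC content and neighbouring genes were chosen after the result was seen, while the list percentiles matched on mean count and the values without a filter were planned. With 1 library per group none of them can separate the siRNA from the pool of embryos or the library preparation. The numbers given by chance below treat genes as unrelated. Beyond the lists fixed in advance, families of genes that share the start of a symbol were examined. Of 27 families with at least 20 measured members, 3 lay outside the middle 95% of lists matched on mean count, where 1.35 would by chance. They were Rpl (median log2 ratio -1.17), Rps (-0.96) and Ube, the ubiquitin-conjugating enzymes and related genes, at -0.56 over 27 genes. When matched on length, 2 families were outside: Ube, and Rpl at percentile 2.36, while Rps lay at 11.7. Rpl and Rps largely repeat the ribosomal protein list, which leaves Ube as the 1 other family outside, no more than the number given by chance. The Ube family had 6 genes at least 2-fold lower and 3 at least 2-fold higher and lay at percentile 0.64, or 0.28 when matched on length. Mitochondrial ribosomal protein genes (Mrpl) had a median of -0.58 over 27 genes, at percentile 2.96, or 26.6 when matched on length. The 152 zinc finger genes named Zfp had a median of 0.11, with 27 higher and 17 lower, at percentile 94.2.

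Genes of chromosomes 17 and 18 lay on opposite sides of 0. On chromosome 17, 76 of 339 genes were at least 2-fold lower and 35 at least 2-fold higher, with a median log2 ratio of -0.25. On chromosome 18 the median was 0.26 over 189 genes, with 31 at least 2-fold higher and 27 at least 2-fold lower. Over all genes these shares were 12.5% higher and 16.7% lower. Against lists matched on length, GC content and mean count these medians lay at percentiles 0.07 and 99.9, and of the 20 chromosomes compared these 2 were outside the middle 95%, where 1 would be by chance. Matched on mean count alone, 5 were outside. The X chromosome, with Xist 1.88-fold higher, had a median of 0.0045, at percentile 45.2.

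Even counts were more frequent than odd ones at low values. In the siDnmt1 library 1225 genes had an even count from 6 to 18, against 1085 expected from the neighbouring odd counts, and in the scrambled library 1188 against 1052. The counting intervals treat every count as independent.

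The first pattern is the lower median of ribosomal protein (-1.23), respiratory chain (-1.20) and proteasome (-0.53) genes. A GC content trend is argued against as the whole cause, since lists matched on GC content and mean count left them at percentiles 0.00, 0.00 and 0.05. A length trend may contribute but the corrections split, and the rule that a split decides nothing was itself set after the splits were seen: among lists matched on longest transcript length they lay at percentiles 0.11, 3.90 and 24.06, after removal of the trend at 14.03, 2.43 and 27.9, and among lists matched on median transcript length at 0.00, 0.00 and 1.13. The genes matched to ribosomal protein genes were longer than these (median 1248 against 1082 nt), and the median transcript length followed the log2 ratio less closely (rho 0.13 against 0.24). For ribosomal protein genes the split rests on the trend removal alone, whose curve was fitted with list members included. A different point of development stays open too. The maternal list lay at percentile 72.19 with members on both sides of 0, which decides nothing. The filtered median of MERVL-linked genes lay at percentile 19.83. Their mean of -0.57 (percentile 2.43) and their median of -0.47 without the filter (percentile 0.71) stood apart lower. Length was taken into account for neither value, so they leave the question open.

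The second pattern is the higher median of RNA interference genes (0.78) and paternally expressed imprinted genes (0.90). Long transcripts were higher in siDnmt1 in general, yet RNA interference genes lay at percentile 99.71 and the imprinted genes at 99.00 among length-matched lists, at 99.1 and 98.4 after the length trend was removed, and at 99.9 and 99.2 when median transcript length was matched. With GC content matched they lay at percentiles 99.95 and 99.27. Length and GC trends are thus argued against as the whole cause of these filtered medians. The rules for this were set after the values were seen, and list means were not corrected. A difference between the pools unrelated to Dnmt1 remains open, as does the siRNA itself. The imprinted list rests on 9 genes and on the filter, since its median was 0.064 without it. Its filtered median is also the value of 1 middle member, with the next lower member at 0.18.

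The third pattern is the small difference in Dnmt1 itself beside the larger one in Uhrf1. Among the 200 genes nearest in mean count, 57 had a lower log2 ratio than Dnmt1 (percentile 28.5), so its value is consistent with the ordinary spread between these libraries. Uhrf1 lay at percentile 2.00 among its own 200 neighbours. It is the lowest of the 17 measured DNA methylation genes, of which 12 had a log2 ratio above 0. The percentile of such a selected extreme does not show that Uhrf1 is exceptional. Whether the siRNA lowered Dnmt1 mRNA earlier than the stage sampled was not tested.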
